A study of Mus musculus with 5 samples.

How the data were processed

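Poly-A selected RNA from hearts of 6-month-old mice was sequenced in 5 libraries. Per the labels, 2 came from wild-type (WT) mice, 1 female and 1 male, and 3 from db/db mice, 2 females and 1 male. The db/db mouse is homozygous for a splicing mutation in the leptin receptor gene Lepr and becomes obese and diabetic. Per the labels' protocols, the growth conditions were described for male mice, whereas the sample labels give 3 females, and the labels name the KsJ background only for the db/db genotype. The labels do not state that each library came from a separate animal, so the p-values measure the spread between these samples.

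The submitters' processing notes name HISAT, Bowtie2 and DESeq2 without version or role, and the mouse build GRCm38.p6. The authors deposited 1 table of coding genes with 3 kinds of values per sample. Per the file headers, it held the authors' estimated read counts, FPKM values and TPM values. The deposited estimated counts (expected counts) were made by the authors with a counting program that is not given in the sources used here; they were not normalized, and 91.4% were exactly whole as printed in the table, with no tolerance. The deposited FPKM values are scaled to gene length and library size, and the deposited TPM values were read but not tested. The table also held the authors' deposited log2 fold changes, p-values and q-values for db/db against WT. After 1 line that held a text fragment was dropped, 17228 genes remained. For 23 genes the symbol had been turned into a date and was restored through the NCBI gene ID, and 17120 genes had their ID in a RefSeq annotation of the same build. Genes of the mitochondrial genome were not analysed here.

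The estimated counts were rounded to whole numbers. The totals per library ran from 8356099 to 10381326 counts. A count of 0 allows up to 3 counts, which was 0.292 to 0.405 CPM (counts scaled to the library size), and this covers counting error only. The edgeR filter for low counts left 12540 genes. Counts were scaled with TMM factors and tested with edgeR 4.0.16 in R 4.3.3, by the robust quasi-likelihood F test with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Genotype was tested alone (3 residual degrees of freedom), sex was tested in a model with genotype, and the interaction of genotype and sex in a model with 1 residual degree of freedom, which came from the 2 db/db females. Standard errors (SE) of log2 fold changes were derived from the F statistics. CPM values are TMM-scaled means ± SD.

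The lists of genes, 49 in all, were fixed before the data were examined, and the 44 with at least 3 tested members were tested with camera in limma 3.58.1. Camera used a preset correlation of 0.01 between genes and, as an alternative, an estimated correlation. Scores per sample were mean log2 CPM values (prior count 2) minus the WT mean and were compared by an exact permutation test over the 10 splits of 5 samples into 2 and 3, in which the smallest two-sided p is 0.1. Gene Ontology terms paired with genes in the deposited table were tested in the same way where they had 10 to 200 tested genes.

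The rule for naming genes was also fixed before the data were examined. It took the 10 genes with the largest log2 fold change in each direction among called genes with a mean of at least 5 CPM in the higher group, non-overlapping groups and no predicted-gene name. It added up to 2 genes per list and always Lepr, Mybpc3, Myh6, Myh7, Nppa and Nppb. For sex it took the 5 genes with the smallest p in each direction, and for the interaction the 5 with the smallest p. Genes named beside these were chosen after their values were seen.

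The alternatives were DESeq2 1.42.0, limma-voom, RLE scaling, library totals, 2 other filters on low counts, a threshold of 0.5 on the log2 fold change, sex or the number in the sample title as a covariate, females alone, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes over 1 FPKM in 2 samples, and leaving out each library. Where this or the choice of females left 1 WT library, the lone library was assumed to vary like the db/db libraries. Chosen after seeing the data were an offset for each library's trend with gene length and GC content (loess, span 0.3), the same offset with sex as a covariate, and leaving out both the WT female and the db/db male. The trend was fitted on genes with a mean log2 CPM over 2. Gene length was taken as the length implied by the deposited counts and FPKM. GC was taken from the longest GENCODE M21 transcript, which 98.9% of tested genes had.

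The tests were tried on simulated counts for the 12540 genes with 200 changed genes and no trend with gene length. For db/db against WT, edgeR recovered 88 of 100 genes changed 2-fold and 98 of 100 changed 4-fold, and 6.06% of its calls were unchanged genes. For male against female these values were 88, 99 and 13.4%. For the interaction they were 14, 81 and 28.6%. In a separate simulation of db/db against WT, genes were drawn independently and only 1 gene list was raised 2-fold. This list had a camera adjusted p of 5.19e-54 with the preset correlation, and its adjusted p was 0.0841 with an estimated correlation. In the real data the estimated correlation was, for example, -0.03 for lipid storage and 0.42 for glucocorticoid-responsive genes. The simulation therefore does not show which setting holds for the real lists. Figures were drawn with matplotlib 3.10.9.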

Results

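Gene expression was measured in 5 heart samples from mice at 6 months of age, 2 WT and 3 db/db. The aim was to follow the heart in diabetes caused by the splicing mutation in the leptin receptor gene. The libraries held 9119182 counts (WT female), 8895194 counts (WT male), 9964739 and 10381326 counts (db/db females 1 and 2) and 8356099 counts (db/db male). Between 14685 and 15132 genes were detected per library, and the 10 most abundant genes took 14.0% to 17.1% of counts.

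Lepr, the leptin receptor gene that carries the db mutation (chromosome 4, 101717134 to 101815354 in GRCm38.p6), had 37 and 14 counts in the WT samples and 3, 7 and 5 counts in the db/db samples. Its mean was 2.56 ± 1.47 CPM (SD, n = 2) in WT and 0.556 ± 0.217 CPM (SD, n = 3) in db/db. Lepr had a log2 fold change of -2.21 (SE 0.56), lower in 3 of 3 db/db samples, and missed the threshold (edgeR adjusted p = 0.106); it passed with sex as a covariate (adjusted p = 0.0263) and without the filter on low counts (0.0361). It also passed in females alone (0.000428), where the WT arm was the single WT female with the 37 counts, and without this library its log2 fold change was -1.45 (adjusted p = 0.91). The counts cover all isoforms and do not read the mutation itself. Mybpc3, which encodes the cardiac myosin-binding protein C whose phosphorylation the study examined (chromosome 2, 91118022 to 91136573), was at 3822 ± 397 CPM (SD, n = 2) in WT and 4572 ± 498 CPM (SD, n = 3) in db/db. Its log2 fold change was 0.26 (SE 0.17, adjusted p = 0.535). The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y matched the sex labels in all 5 samples: Ddx3y had 453 and 525 counts in the males and 0 to 1 counts in the females.

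The comparison of db/db with WT asked which heart transcripts change in diabetes. Ciart, a repressor of the circadian clock (chromosome 3, 95878500 to 95882242), rose from 2.23 ± 0.84 CPM (SD, n = 2) to 23.9 ± 7.5 CPM (SD, n = 3), a log2 fold change of 3.39 (SE 0.33, adjusted p = 0.000785). Timp4, a cardiac inhibitor of matrix metalloproteinases, rose from 33.4 ± 2.9 to 166 ± 50 CPM, a log2 fold change of 2.31 (SE 0.25, adjusted p = 0.00183). Aplnr, the receptor of apelin, fell from 89.3 ± 20.5 to 24.2 ± 6.7 CPM, a log2 fold change of -1.87 (SE 0.22, adjusted p = 0.00315). Adam19, a membrane metalloprotease, fell from 42.0 ± 2.7 to 12.6 ± 0.3 CPM, a log2 fold change of -1.74 (SE 0.15, adjusted p = 0.000572). Each of these 4 genes kept its call in 20 of 20 alternatives.

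The naming rule ranked only called genes with a mean of at least 5 CPM in the higher group, non-overlapping groups and no predicted-gene name. Among these, the other genes with the largest increases were Kcnk1, a background potassium channel (log2 fold change 3.17), Arrdc2 (2.88), the stanniocalcin gene Stc1 (2.46), Fam107a (2.42), Slc10a6 (2.32), the cysteine dioxygenase gene Cdo1 (2.32), the cytochrome P450 gene Cyp2b10 (2.28) and the kinase gene Map3k6 (2.21). By the same rule, the other genes with the largest decreases were Tgtp1 (-2.10) and Gbp4 (-1.97), which encode interferon-induced GTPases, Spon2 (-1.93), the MHC class I-like gene H2-Q8 (-1.86), Prnd (-1.83), Apol10b (-1.82), Tmem171 (-1.71) and the clock activator Arntl (-1.63). Tgtp1 and H2-Q8 may share reads with near-identical copies, which was not tested, so their values are uncertain. Of the genes in this paragraph, 11 lost their call without the WT female, with adjusted p from 0.0608 (Slc10a6, Map3k6) to 0.34 (Tgtp1). Without the WT male 7 did, from 0.0574 (Slc10a6) to 0.196 (Tmem171), and without db/db female 1 Cyp2b10, Apol10b and Tmem171 did (0.0721 to 0.0784). Tgtp1 also lost it without db/db female 2 (0.136), and Tgtp1 and Gbp4 did without the db/db male (0.253 and 0.255). The folds moved both ways without the WT female: the log2 fold change shrank to -1.33 for Tgtp1 and grew to 2.82 for Stc1.

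In all, 129 of 12540 genes passed, 84 higher and 45 lower in db/db, and 91 of them changed at least 2-fold; 1623 genes had an unadjusted p under 0.05. The authors' deposited table listed 221 genes with q under 0.05 among 16369 genes, 156 higher and 65 lower, and 127 of the 129 were among the authors' 221 with the same sign. With library totals in place of TMM the split was 59 higher and 85 lower, and with limma on log2(FPKM + 1) and log2(FPKM + 0.1) it was 56 and 56, and 56 and 50; the median log2 fold change of all genes was then -0.19, -0.15 and -0.17. The count was 832 with sex as a covariate, 974 in females alone (1 WT library), 256 without the filter on low counts, 241 with DESeq2 and 40 against a log2 fold change of 0.5. It was 25 without the WT female, 67 without the WT male, 49 without db/db female 1 and 244 without the db/db male, and 433 without both the WT female and the db/db male.

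**Figure D1:**
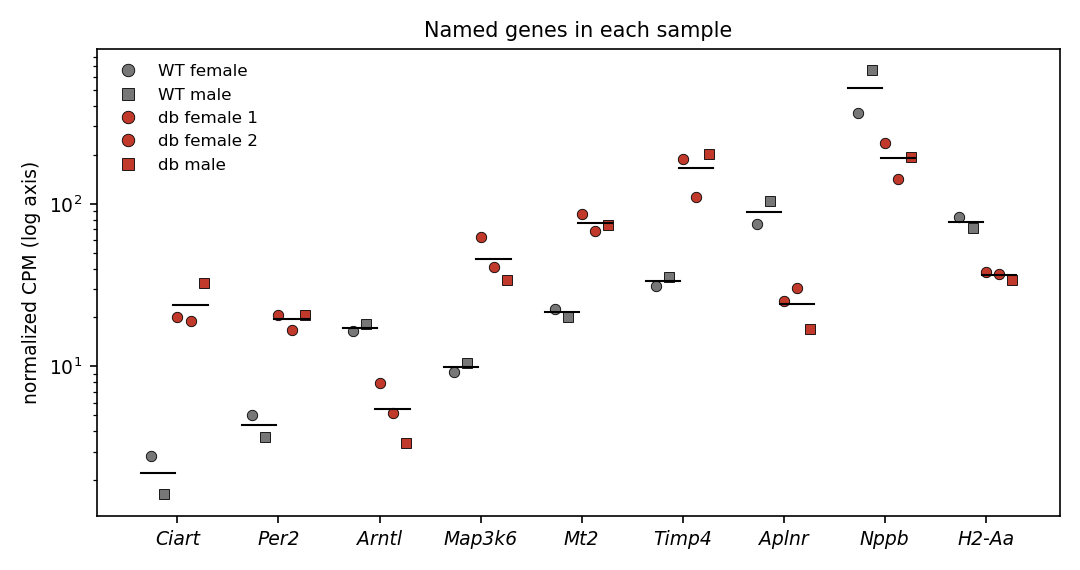
Normalized CPM (log axis) of 9 named genes in each sample, with circles for females, squares for males, grey for WT, red for db/db and black lines for group means. The means of Ciart were 2.23 CPM in WT and 23.9 CPM in db/db.

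Of the 44 gene lists tested, the glucocorticoid-responsive genes had the smallest p by camera with the preset correlation, all 5 samples and no term for sex. Without the WT male the respiratory chain came first. With sex as a covariate the camera adjusted p was smaller for the respiratory chain (5.94e-32 against 2.48e-20). With an estimated correlation their camera unadjusted p was 0.0272. It was then smaller for antigen presentation (0.0114), lipid storage and synthesis (0.0177) and white adipocyte markers (0.0248). Of the glucocorticoid-responsive genes, 12 of 19 tested members rose, none fell and 7 did not pass, and 17 rose when adjusted over the list alone. Their median log2 fold change was 1.41. Hif3a had 3 and 5 counts in the WT samples and 16 to 46 in the db/db samples, a ratio of 8.34 (95% counting interval 4.06 to 19.9; adjusted p = 0.0276). Map3k6 had a log2 fold change of 2.21 (adjusted p = 0.00315), and the metallothionein genes Mt2 and Mt1 had 1.83 (adjusted p = 0.000572) and 1.31 (adjusted p = 0.0132). Mt1, Mt2, Per1, Lcn2, Pdk4, Angptl4 and Dusp1 are also in other lists. Without the WT female Hif3a, Map3k6 and Mt1 lost their calls (adjusted p = 0.315, 0.0608 and 0.217), and Hif3a and Mt1 also did without the WT male (0.11 and 0.0707) and without db/db female 1 (0.128 and 0.0684). The list's camera adjusted p was 7.98e-26, and adjusted p = 0.281 with an estimated correlation. Its score, relative to the WT mean, was 1.08 to 1.66 in the db/db samples and -0.06 and 0.06 in the WT samples.

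Of 19 circadian clock genes, 5 rose, 1 fell and 13 did not pass; adjusted over the list alone, 7 rose and 3 fell. Besides Ciart, the period genes Per2 (2.14, adjusted p = 0.000942) and Per1 (1.59, adjusted p = 0.0127) and the output genes Dbp (1.69, adjusted p = 0.00639) and Tef (1.02, adjusted p = 0.0196) rose on the log2 scale. Arntl, the partner of Clock, had -1.63 (adjusted p = 0.0172). Without the WT male Per1, Dbp, Tef and Arntl lost their calls (adjusted p from 0.0574 to 0.167), as did Arntl and Tef without the WT female (0.136 and 0.207) and Per1 without the db/db male (0.0756). The list's median was 0.31, and 0.19 without the WT male, with a camera adjusted p of 0.00243, and adjusted p = 0.372 with an estimated correlation. Immediate early genes did not pass: 0 of 22 members were called by edgeR, DESeq2 or limma-voom (3 at an unadjusted p under 0.05), with a median of 0.23 (camera adjusted p = 0.101), and their score was 0.94, -0.04 and -0.32 in the db/db samples against -0.32 and 0.32 in the WT samples.

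**Figure D2:**
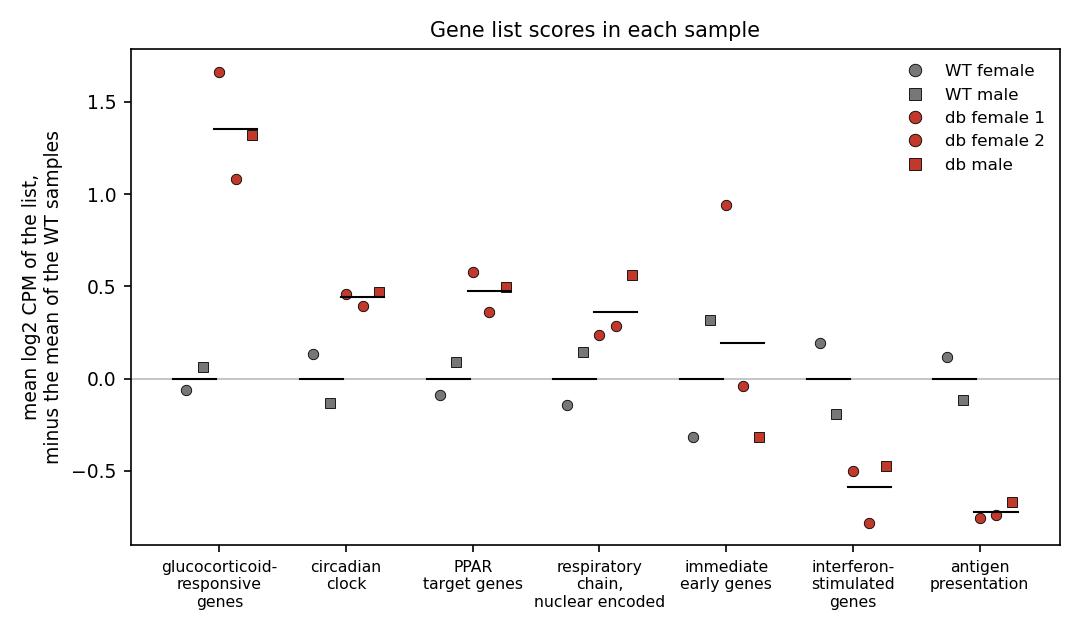
Mean log2 CPM of 7 gene lists in each sample minus the mean of the WT samples, with circles for females, squares for males, grey for WT, red for db/db and black lines for group means. The glucocorticoid-responsive genes scored 1.08 to 1.66 in the db/db samples, and the antigen presentation genes -0.76 to -0.67.

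In the lists of lipid use most members had positive values, but few passed singly. The 5 white adipocyte markers tested also had a positive median (0.78), and Lipe is 1 of them. Of 22 targets of the lipid-sensing receptors PPAR, 1 rose and 21 did not pass, and 10 rose when adjusted over the list alone. The median was 0.41. The PPAR list is not independent of others: Pdk4 and Angptl4 are also in the glucocorticoid-responsive list. It shares Plin2, Plin5 and Mgll with lipid storage and synthesis, and Cpt1a and Slc25a20 with mitochondrial fatty acid oxidation. Of 28 genes of lipid storage and synthesis, 1 rose, the hormone-sensitive lipase gene Lipe (0.90, adjusted p = 0.0276), and 7 rose when adjusted over the list alone; the median was 0.29. Lipe lost its call without the WT female (adjusted p = 0.217), the WT male (0.197) or db/db female 1 (0.123), with library totals (0.0704) and with limma on both FPKM scales (0.0809 and 0.0882). The camera adjusted p values were 6.67e-10 for PPAR targets and 0.000121 for lipid storage, and for both lists adjusted p = 0.281 with an estimated correlation. Of 22 genes of mitochondrial fatty acid oxidation, 0 passed by edgeR, 9 at an unadjusted p under 0.05, 3 by DESeq2, 0 by limma-voom and 0 when adjusted over the list alone, although 18 had positive values. The median was 0.28, and 0.19 without the WT female; Acaa2 had 0.67 (adjusted p = 0.153) and Acadvl 0.51 (adjusted p = 0.198). Its camera adjusted p was 6.42e-06, and adjusted p = 0.372 with an estimated correlation. Of 25 genes of glucose uptake and glycolysis, 1 rose, Pfkfb1 (1.17, adjusted p = 0.0127), as when adjusted over the list alone, where 1 also fell; Pfkfb1 lost its call without the WT female (adjusted p = 0.132), the WT male (0.114) or db/db female 1 (0.065). The median was 0.20, and 0.32 without the WT male, with a camera adjusted p of 0.00267, and adjusted p = 0.372 with an estimated correlation. With sex as a covariate, 6 of the fatty acid oxidation genes passed, all higher, among them Acaa2 (0.73, adjusted p = 0.00168; 0.0199 with DESeq2 and no sex term) and Acadvl (0.54, adjusted p = 0.00776; 0.0432 with DESeq2 and no sex term). In the same model 8 PPAR targets, 8 lipid storage genes and 6 glycolysis genes passed as higher, and 1 glycolysis gene as lower. With library totals the medians were 0.23 for PPAR targets, 0.11 for lipid storage, 0.10 for fatty acid oxidation and 0.022 for glucose uptake and glycolysis, where the median of all genes was -0.19.

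The nuclear-encoded respiratory chain had 70 of 73 members with positive values and a median log2 fold change of 0.40, but 0 passed by edgeR over all genes or when adjusted over the list alone (33 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom), and Ndufs5 had 0.79 (adjusted p = 0.134; 0.0135 with DESeq2, 0.0364 without the filter on low counts). The ventricular cardiomyocyte markers also had a positive median (0.34, camera adjusted p = 0.0229, and adjusted p = 0.372 with an estimated correlation). With the length and GC offset their median was 0.16 (camera adjusted p = 0.178). For the respiratory chain the camera adjusted p was 2.75e-17, and adjusted p = 0.404 with an estimated correlation. With sex as a covariate, 45 of the 73 passed, all higher. These are short genes, with a median length of 628 bases against 2771 for all tested genes, and short genes were read less in the WT female and more in the db/db male. Tested genes with a mean log2 CPM over 2 were put into 10 bins by length. In the shortest bin the median deviation was -0.28 in the WT female and 0.28 in the db/db male, against -0.02 to 0.01 in the other libraries. Within each genotype the male thus lay higher, so a sex term can take up part of the trend's spread. As a set, the 45 calls with sex as a covariate therefore cannot be told apart from the trend. With the length and GC offset beside sex, Ndufs5 still passed (0.51, edgeR adjusted p = 0.0155), against 0.89 with sex alone (0.000476). The other members were not counted in that fit. Over all genes the count with sex as a covariate was 832, and 416 with the length and GC offset as well. With the offset for gene length and GC content the list's median was 0.15. With no offset it was 0.25 without the WT female, 0.26 without the db/db male and 0.11 without both libraries. The offset left the median of the glucocorticoid-responsive genes at 1.33 and that of the antigen presentation genes at -0.78.

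**Figure D3:**
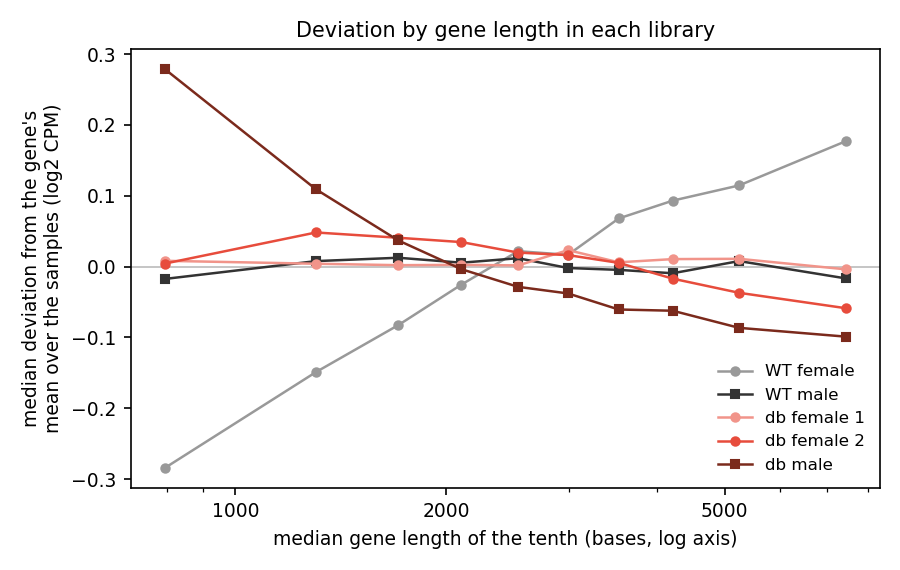
Median deviation of genes from their mean over the 5 samples (log2 CPM), with 1 line per library. Tested genes with a mean log2 CPM over 2 were put into 10 bins by length (log axis). In the bin of the shortest genes the WT female lies at -0.28 and the db/db male at 0.28.

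Genes of antigen presentation were lower: 4 of 13 fell, none rose and 9 did not pass, and 10 fell when adjusted over the list alone. The median was -0.66. The 3 B cell markers tested also had a negative median (-1.14, camera adjusted p = 0.0212, and adjusted p = 0.404 with an estimated correlation). The 15 macrophage markers had a median of -0.11 (camera adjusted p = 0.465), 6 of them positive, with Cx3cr1 at -1.53 (edgeR adjusted p = 0.0546). The antigen presentation genes past the threshold all act in MHC class II presentation: H2-Eb1 (-1.13, SE 0.16, adjusted p = 0.00868), H2-Aa (-1.08, SE 0.14, adjusted p = 0.00408), H2-Ab1 (-1.0, adjusted p = 0.0162) and the invariant chain gene Cd74 (-0.85, adjusted p = 0.0334). H2-Aa was at 77.2 ± 8.2 CPM (SD, n = 2) in WT and 36.5 ± 2.1 CPM (SD, n = 3) in db/db. All 4 lost their calls without the WT female (adjusted p from 0.0909 for H2-Aa to 0.337 for Cd74), H2-Ab1 and Cd74 without the WT male (0.114 and 0.126), H2-Eb1, H2-Ab1 and Cd74 without db/db female 1 (0.0561, 0.09 and 0.18) and Cd74 without db/db female 2 (0.0758). The list's camera adjusted p was 7.18e-13, and adjusted p = 0.281 with an estimated correlation. Of 28 interferon-stimulated genes, 3 fell, none rose and 25 did not pass, and 15 fell when adjusted over the list alone; the median was -0.55, and -0.32 without the WT female. Among them were Gbp4 (-1.97, adjusted p = 0.0127) and Gbp3 (-1.28, adjusted p = 0.0242). Both lost their calls without the WT female (adjusted p = 0.133 and 0.4), Gbp3 without db/db female 1 (0.0566) and Gbp4 without the db/db male (0.255). The camera adjusted p was 8.77e-12, and adjusted p = 0.372 with an estimated correlation.

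The list written to check for strain differences held 7 tested genes, of which the H2 genes H2-Q7 (-1.56, adjusted p = 0.00993) and H2-Eb1 fell and 5 did not pass, while 5 fell when adjusted over the list alone. H2-Q7 and H2-Eb1 lost their calls without the WT female (adjusted p = 0.165 and 0.138) and without db/db female 1 (0.0566 and 0.0561). The list's median was -0.51 (camera adjusted p = 1.58e-06, and adjusted p = 0.372 with an estimated correlation). Nnt, which carries a deletion in some C57BL/6 stocks, had 4019 and 2653 counts in WT and 1685 to 3470 counts in db/db. Counts over the whole gene do not read a deletion within it. Of 22 cytokine, chemokine and adhesion genes, 1 rose, Lcn2 (1.58, adjusted p = 0.0424), and adjusted over the list alone 3 rose and 2 fell; the camera adjusted p was 0.748. Lcn2 lost its call without the WT female (adjusted p = 0.356), the WT male (0.214) or db/db female 1 (0.18), with limma-voom (0.121), with library totals (0.0727) and with the length and GC offset (0.0881).

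Among antioxidant genes, 3 of 32 rose, Mt2, Mt1 and the glutathione transferase gene Gsta4 (0.96, adjusted p = 0.0329), and 6 rose when adjusted over the list alone. Gsta4 lost its call without the WT female (adjusted p = 0.4), db/db female 1 (0.152) or db/db female 2 (0.0525), and Mt1 without the WT female (0.217), the WT male (0.0707) or db/db female 1 (0.0684). The median was 0.21 (camera adjusted p = 1.33e-06, and adjusted p = 0.365 with an estimated correlation). In the list of haemodynamic stress and fetal genes, 1 of 15 members fell, 4 when adjusted over the list alone, where 1 rose. Nppb, which encodes B-type natriuretic peptide, was at 511 ± 210 CPM (SD, n = 2) in WT and 190 ± 47 CPM (SD, n = 3) in db/db, a log2 fold change of -1.43 (SE 0.26, adjusted p = 0.0334). Nppb lost its call without the WT male (-0.93, adjusted p = 0.19) and without the db/db male (-1.44, adjusted p = 0.439), as well as with sex as a covariate (-1.30, adjusted p = 0.141) and without the filter on low counts (-1.43, adjusted p = 0.0709). Nppa, the atrial natriuretic peptide gene, had -0.58 (SE 0.18, adjusted p = 0.199) and passed with sex as a covariate (-0.53, adjusted p = 0.0184), in females alone (1 WT library; 0.00203), with library totals (-0.77, adjusted p = 0.0343), with limma on both FPKM scales (0.0398 and 0.0452), without the db/db male (-0.71, adjusted p = 0.0162) and with the length and GC offset (-0.85, adjusted p = 0.00831). Myh6 and Myh7, the myosin heavy chain genes of the heart, had 0.31 (SE 0.18, adjusted p = 0.482) and 0.56 (SE 0.72, adjusted p = 0.795). The list's median was -0.27 (camera adjusted p = 0.00767, and adjusted p = 0.372 with an estimated correlation); the list lost its call without the WT male (-0.06, adjusted p = 0.247) and without db/db female 2 (-0.23, adjusted p = 0.088). Of 25 sarcomere genes, 1 rose over all genes and when adjusted over the list alone, the titin cap gene Tcap (1.40, SE 0.28, adjusted p = 0.0456), which lost its call without the WT female (adjusted p = 0.4), the WT male (0.196) or db/db female 1 (0.083), as well as with DESeq2 (0.0746) and with RLE scaling (0.0503). The sarcomere median was 0.26 (camera adjusted p = 0.000124, and adjusted p = 0.408 with an estimated correlation), and 0.09 without both the WT female and the db/db male (camera adjusted p = 0.198).

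Kinases and phosphatases that act on myosin-binding protein C had 0 of 24 members called, with a median of -0.14 (camera adjusted p = 0.181). Calcium handling had 0 of 23 called and a median of 0.08 (camera adjusted p = 0.595; -0.11 with library totals), and insulin signalling 0 of 22 and -0.11 (camera adjusted p = 0.465), with Irs1 at -0.98 (adjusted p = 0.193; 0.0452 with DESeq2 and 0.00111 with sex as a covariate). These counts of 0 by edgeR were the same when adjusted over the list alone and with limma-voom; at an unadjusted p under 0.05 they were 2, 1 and 4, and DESeq2 called 0, 0 and 1. Of 41 extracellular matrix genes, 2 rose, Timp3 (0.95, adjusted p = 0.0152) and Mfap5 (1.0, adjusted p = 0.0474), and the same number when adjusted over the list alone; the median was 0.03, and -0.14 with library totals (camera adjusted p = 0.363). Single members of other lists that passed were Agt, the angiotensinogen gene (1.62, adjusted p = 0.00336), the potassium channel gene Kcna5 (0.85, adjusted p = 0.0325), Herpud1 of the endoplasmic reticulum (0.78, adjusted p = 0.0293) and the heat shock gene Hsph1 (-0.80, adjusted p = 0.0324). Timp3, Mfap5, Kcna5, Herpud1 and Hsph1 lost their calls without the WT female, the WT male or db/db female 1 (adjusted p from 0.0914 to 0.52), Mfap5, Kcna5, Herpud1 and Hsph1 without db/db female 2 (0.0543 to 0.0732), and Agt without the WT female (0.0729). Ketone body metabolism (median 0.03, camera adjusted p = 0.595), ion channels (-0.06, 0.596) and adrenergic signalling (-0.02, 0.761) did not pass by camera, which tests for a common direction. Neither did endoplasmic reticulum stress (-0.17, 0.152), heat shock (-0.05, 0.574), protein degradation (0.05, 0.152) or branched-chain amino acid catabolism (0.11, 0.152). Cell cycle genes had 0 of 22 called by edgeR, DESeq2 or limma-voom or when adjusted over the list alone (4 at an unadjusted p under 0.05), with a median of -0.34 and Mki67 at -0.93 (adjusted p = 0.268). The list's camera adjusted p was 0.00638, and adjusted p = 0.451 with an estimated correlation; without the WT male it was 0.273 (median -0.11). The median was -0.55 without the WT female and -0.59 without db/db female 1.

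Markers of most cell types did not differ by camera. The medians were 0.06 for endothelial cells (camera adjusted p = 0.468) and 0.00 for fibroblasts (0.574), both negative with library totals (-0.11 and -0.17), -0.09 for mural cells (0.924), -0.11 for macrophages (0.465) and 0.34 for ventricular cardiomyocytes (camera adjusted p = 0.0229, and adjusted p = 0.372 with an estimated correlation). The cardiomyocyte markers lost their call without the WT female (0.23, adjusted p = 0.0654), without db/db female 2 (0.40, adjusted p = 0.0597) and with the length and GC offset (0.16, adjusted p = 0.178). Among macrophage markers Cx3cr1 had -1.53 (adjusted p = 0.0546), and passed with DESeq2 (0.0285), library totals (0.0335), no filter on low counts (0.0108), sex as a covariate (0.0183) and without the db/db male (0.0378). The 5 white adipocyte markers tested had a median of 0.78, 1 of them past the threshold (Lipe) and 4 when adjusted over the list alone (camera adjusted p = 0.000162, and adjusted p = 0.281 with an estimated correlation). The 3 B cell markers tested had a median of -1.14 (camera adjusted p = 0.0212, and adjusted p = 0.404 with an estimated correlation), with Cd79a at -1.14 (adjusted p = 0.342); the list lost its call without the WT male (adjusted p = 0.0983), without db/db female 2 (0.145) and with sex as a covariate (0.0869). The 9 Schwann cell and neuron markers had a median of 0.62 (camera adjusted p = 0.0355, and adjusted p = 0.372 with an estimated correlation), with 0 members called by edgeR, DESeq2 or limma-voom (3 at an unadjusted p under 0.05), and no call without the WT female, the WT male, db/db female 1 or db/db female 2 (adjusted p from 0.0524 to 0.0983; median 0.40 without the WT female and 0.41 without the WT male) or with sex as a covariate (0.0894). The 8 erythroid markers had a median of 0.31 (camera adjusted p = 0.0158, and adjusted p = 0.636 with an estimated correlation), and the WT female stood apart with a score of -0.67 against 0.30 to 0.67 in the other samples. Without the WT female the erythroid median was -0.25 (adjusted p = 0.0654), without the WT male 1.21, without db/db female 2 0.24 (adjusted p = 0.103) and with the length and GC offset 0.13 (adjusted p = 0.127). Of the lymphatic markers, Lyve1 rose (1.05, adjusted p = 0.0127) while Prox1 fell (-0.99, adjusted p = 0.0236); both lost their calls without the WT female (0.118 and 0.385) and db/db female 1 (0.0784 and 0.114), and Lyve1 without the WT male (0.118). The liver marker Ahsg rose from 2.11 ± 0.10 to 7.29 ± 1.49 CPM (adjusted p = 0.0173), but not without the WT female (0.21) or the WT male (0.112). The 3 liver markers tested had a median of 1.64 (camera adjusted p = 0.0129, and adjusted p = 0.372 with an estimated correlation), and no call without the WT female (1.23, adjusted p = 0.0587). Atrial cardiomyocyte (0.01, camera adjusted p = 0.965), lymphatic (0.26, 0.363), neutrophil (-0.18, 0.363), brown adipocyte (0.31, 0.0651), skeletal muscle (-0.08, 0.163) and epicardial markers (0.48, 0.179) did not pass by camera. T and NK cell (1 of 14 members tested), thymus (2 of 8) and lung epithelium markers (1 of 7) were too few for a list test.

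By camera with the preset correlation, 20 of 44 lists passed, 14 higher and 6 lower. None passed with an estimated correlation, where 6 had an unadjusted p under 0.05. The directional test of fry called 1. Its mixed test, which asks for change in either direction, called 20, of which 10 were among camera's 20. The others included ketone body metabolism, insulin signalling, ion channels, adrenergic signalling and cytokines, chemokines and adhesion molecules (fry mixed adjusted p from 0.03 to 0.0416). Endoplasmic reticulum stress (0.0361), heat shock (0.0212), protein degradation (0.0388), macrophage (0.0398) and lymphatic markers (6.22e-06) were also among them. A mixed call gives no direction. The medians above are TMM values. With library totals the antioxidant median was 0.044 against 0.21, the sarcomere median 0.071 against 0.26, the clock median 0.11 against 0.31, the respiratory chain median 0.21 against 0.40, and the medians of cardiomyocyte and erythroid markers both 0.15 against 0.34 and 0.31. The negative medians grew, to -0.46 for haemodynamic stress and fetal genes and -0.52 for cell cycle genes. The sign of the median held for all 20 lists with RLE, library totals and both FPKM pseudocounts. Of the genes named above, Gsta4, Herpud1, Kcna5, Lyve1 and Mfap5 also lost their calls with library totals (adjusted p from 0.0583 to 0.13) and, with Prox1 and Timp3, with limma on both FPKM scales (0.0547 to 0.189). Hif3a (0.0817), Mfap5 (0.0608) and Tgtp1 (0.0544) lost theirs with limma-voom, Mfap5 with the length and GC offset (0.0713), and Per1 and Dbp with that offset and sex (0.0535 and 0.096). Scores separated the groups completely for lists such as the glucocorticoid-responsive and antigen presentation genes, where the exact permutation p was 0.1, the smallest that 2 against 3 samples can give.

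The comparison of males with females, in a model with genotype, first showed the sex chromosomes. The Y-linked genes Ddx3y (adjusted p = 6.31e-10), Eif2s3y (2.67e-07), Uty (7.66e-05) and Kdm5d (0.0012) were higher in both males; Uty and Kdm5d had 0 counts in the females, and Eif2s3y 244 and 308 counts in the males against 0 to 4. Their X-linked partners were lower in males: Eif2s3x had a log2 fold change of -0.99 (SE 0.12, adjusted p = 0.00211), Ddx3x -0.73 (SE 0.11, adjusted p = 0.0148) and Kdm5c -0.83 (SE 0.13, adjusted p = 0.0166). Ppbp, a platelet chemokine gene, was at 12.6 ± 2.7 CPM in males (SD, n = 2) and 2.47 ± 1.03 CPM in females (SD, n = 3), adjusted p = 0.00138. Moap1 had 16 to 37 counts in the females and 0 in the males (adjusted p = 0.019). Scgb1a1, a marker of airway epithelium, had 48 and 94 counts in the db/db females and 0 to 1 in the other samples (adjusted p = 0.0148), with no call without db/db female 2 (0.0561) or the db/db male (0.775).

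In all, 176 genes passed, 154 higher and 22 lower in males. In simulated data 13.4% of this test's calls were unchanged genes. That simulation held no length trend and genes changed 2-fold or 4-fold, whereas 18 of the 176 changed at least 2-fold, so the share here may be larger. Of the 176 genes, 4 lay on the Y chromosome, 5 on the X and 167 elsewhere. Genes higher in males had a median length of 742 bases and those lower in males 4869 bases, against 2771 for all tested genes. With the offset for length and GC content, 32 genes passed, 25 higher and 7 lower. DESeq2 called 289, but it gave an adjusted p to only 4517 genes. No filter on low counts gave 419, and without a genotype term the count was 5. Without that term Ppbp, Moap1, Scgb1a1, Eif2s3x, Ddx3x and Kdm5c lost their calls (adjusted p from 0.0607 to 0.921). With the genotype term kept, the count was 854 without the WT female, 856 without the WT male, 104 without db/db female 1 and 38 without db/db female 2.

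The interaction of genotype and sex asked whether the db/db effect differed between males and females. Among the 5 genes with the smallest p were the early response genes Junb and Cyr61 and 2 globin genes. Junb was 2.40-fold as high in db/db as in WT females and 0.434-fold in males, a log2 difference of -2.47 (SE 0.27, adjusted p = 3.39e-14). Cyr61, which encodes a matricellular protein, was 2.18-fold as high in females and 0.397-fold in males, a log2 difference of -2.45 (SE 0.26, adjusted p = 5.12e-14). The globin genes Hbb-bt and Hba-a1 were 2.38-fold and 2.44-fold as high in db/db females as in the WT female and 0.768-fold and 0.853-fold in males, with log2 differences of -1.63 (adjusted p = 1.27e-10) and -1.51 (adjusted p = 5.63e-10). LOC100862455 had a log2 difference of -2.41, and the near-identical LOC100044627 moved the other way (1.36). The 2 may share reads, which was not tested, so the value of LOC100862455 is uncertain.

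In all, 145 genes passed, 51 with a positive and 94 with a negative difference. This test had 1 library in 3 of its 4 cells, and in simulated data 28.6% of its calls were unchanged genes. DESeq2 called 4 genes, and with the offset for length and GC content the count was 32.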

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

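The interaction test of genotype and sex called 145 genes, but 3 of its 4 groups held 1 library, so that its only residual degree of freedom came from the 2 db/db females; in simulated data 28.6% of its calls were unchanged genes, and DESeq2 called 4 genes. No library was tested as far from the others because each group held fewer than 4. The 5 genes with the smallest p had log2 differences (effect in males minus effect in females) of -2.41 (LOC100862455), -2.47 (Junb), -2.45 (Cyr61), -1.63 (Hbb-bt) and -1.51 (Hba-a1). Normalized CPM of Junb was 38.2 in the WT female, 73.8 in the WT male, 114 and 69.5 in the db/db females and 32.0 in the db/db male. For Hba-a1 the WT female stood apart, at 1237 CPM against 2812 to 3680 CPM in the other 4 samples. The copy Hba-a2 may share reads with Hba-a1, which was not tested. With DESeq2, 2 of the 5 kept their call. With the length and GC offset, a test chosen after the result was seen, 2 of the 5 did, while the log2 differences of the others were -2.39 (Junb), -2.39 (Cyr61) and -1.66 (Hbb-bt), so the lost calls do not speak for or against the trend as a cause.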

How the results depend on the processing

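The length and GC offset, alone or with sex, and leaving out both the WT female and the db/db male were chosen after seeing the data; the other alternatives were planned. Against 129 genes between db/db and WT, DESeq2 gave 241, no filter on low counts 256, sex as a covariate 832, a log2 fold threshold of 0.5 40, females alone 974, the offset with sex 416 and leaving out both libraries 433. With the title number as a replicate block 80 passed, 76 of them among the 129. Correlations between libraries of the same number were 0.10, -0.18 and -0.13, and the others were 0.13, -0.10 and 0.18. With 2 WT libraries centred on their mean, the others are the same values with the sign turned. They cannot show whether the title number marks a batch. Leaving out 1 library gave 25 (WT female) to 244 (db/db male). The other alternatives gave 106 to 151. Of 52 named genes past the threshold none reversed, and 15 kept their call without the WT female, 24 without the WT male, 26 without db/db female 1, 44 without db/db female 2 and 48 without the db/db male. Against a log2 fold of 0.5, 24 kept it, with the replicate block 36, with library totals 45 and with limma-voom 48. The offset left 50 and the offset and sex 48. With limma on either FPKM scale 42 kept it and 8 lost it, while Hif3a and Mstn were not tested there. Without either WT library, 1 WT library is left and the db/db samples alone give the spread, so a call can end with little change in the fold: Stc1 had 2.46, and 2.82 without the WT female and 2.18 without the WT male, Lipe 0.90, 0.96 and 0.85, and Lyve1 1.05, 1.18 and 0.93. Myh7, which was not called, had -0.26 without both libraries. For sex, against 176, DESeq2 gave 289, no filter 419, no genotype term 5 and the offset 32, and leaving out 1 library 38 (db/db female 2) to 856 (WT male). For the interaction, against 145, DESeq2 gave 4 and the offset 32. Of 20 lists, an estimated correlation left 0 and fry's directional test 1, while fry's mixed test called 20 lists, 10 of them among these. The erythroid median was -0.25 without the WT female, 1.21 without the WT male and -0.24 without both libraries. Apart from settings with fewer samples, the cause of these differences was not tested. Leaving out mitochondrially encoded genes was not run, since the table holds none. Depth limits genes with few counts, since a count of 0 allows up to 0.292 to 0.405 CPM.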

Other observations

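Both the apelin gene and its receptor gene were lower in db/db: Apln fell from 25.8 ± 6.9 CPM (SD, n = 2) to 11.7 ± 1.2 CPM (SD, n = 3), a log2 fold change of -1.13 (SE 0.20, edgeR adjusted p = 0.0195), beside the fall of Aplnr. Apln lost its call without the WT male (-0.83, adjusted p = 0.197) and without db/db female 1 (-1.14, adjusted p = 0.0945). Mstn, which encodes the growth inhibitor myostatin, had 1 count in each WT sample and 16 to 30 counts in the db/db samples, a ratio of 23.1 with a 95% counting interval of 6.13 to 194 (adjusted p = 0.0127). Mstn lost its call without the WT female (adjusted p = 0.177), the WT male (0.102) or db/db female 1 (0.0682). Apln and Mstn were chosen after their values were seen.

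Of 1110 Gene Ontology terms, 28 passed by camera with the preset correlation, 21 higher and 7 lower, and 0 passed with an estimated correlation, where 7 had an unadjusted p under 0.05. After the length and GC offset 8 passed, all of them among the 28. Among these, cellular response to interferon-beta (34 genes) had a median log2 fold change of -0.48 before and -0.41 after the offset, and fatty acid beta-oxidation (34 genes) 0.17 and 0.18. Cytoplasmic translation (37 genes) had a median of 0.36 before the offset and 0.08 after (adjusted p = 0.541). Complex I assembly (43 genes) had 0.33 before and 0.11 after (adjusted p = 0.168). Terms close to the lists of the report that did not pass before the offset were response to glucocorticoid (26 genes, median 0.06, adjusted p = 0.217), antigen processing and presentation (17 genes, -0.19, adjusted p = 0.217), cellular response to interferon-gamma (56 genes, -0.003, adjusted p = 0.985), circadian regulation of gene expression (16 genes, 0.08, adjusted p = 0.75), regulation of circadian rhythm (22 genes, -0.13, adjusted p = 0.299) and glycolytic process (24 genes, 0.11, adjusted p = 0.31). The terms in this paragraph were chosen after their values were seen.

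The tests in the paragraphs that follow were chosen after the result was seen, the random lists included; the splits of the samples were planned. Of the 10 splits of the 5 samples into 2 and 3, the real one gave 129 genes and the highest of the others 5. So few splits cannot give a share under 0.05.

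The respiratory chain genes had a median of 0.40, and 10000 random lists matched on length, GC and mean expression had a median of 0.24 and at most 0.34, so the real list lay at percentile 100. The trend may account for much of the list's value, since the offset lowered the median to 0.15 (SD 0.14). Whether the trend is the whole cause cannot be told from these tests. The list's median length was 628 bases, below the median of 794 bases in the bin of the shortest genes with a mean log2 CPM over 2. The random lists were matched in bins over all tested genes. The trend was strongest for the shortest genes, so the matched random genes may be longer and less affected. Genes of a complex vary together more than random lists do, so the percentile is not a p-value. A larger cardiomyocyte share of the RNA would lower markers of other cells, and 55 markers of endothelial cells, fibroblasts, mural cells and macrophages had a median of -0.012 (SD 0.44), 27 of them positive. Ventricular cardiomyocyte markers had 0.34 (camera adjusted p = 0.0229, and adjusted p = 0.372 with an estimated correlation), and 0.16 after the offset (camera adjusted p = 0.178). Members that go both ways leave that explanation open, and it cannot be told apart from an effect of the db/db genotype, which was not tested.

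The higher glucocorticoid-responsive genes kept a median of 1.33 after the length and GC offset, against 1.41 before, which argues against the trend as their cause. An immediate early response at tissue collection would raise the immediate early genes in each db/db sample, and they scored above both WT samples in 1 db/db sample. Clock genes of opposite phase parted between the groups: 9 genes that include the Per genes and Dbp had a median of 1.02 and the 3 genes Arntl, Npas2 and Clock -1.32, a difference of 2.33. Another time of day of collection could give such a shift and cannot be told apart from a genotype effect on the clock or on glucocorticoids, since the labels used here give no time of collection. Whether the db/db mice were exposed to more glucocorticoid was not tested.

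The lower antigen presentation and interferon-stimulated genes, 41 in all, had a median of -0.60 before and -0.66 after the length and GC offset, which argues against the trend as the cause. The labels name KsJ only for db/db, and variants in H2 genes against the reference could lower their counts; however, the 29 members outside chromosome 17, which holds the H2 genes, had a median of -0.60 (SD 0.43), 28 of them negative. For the 12 members on chromosome 17, with a median of -0.56, this cannot be told apart from lower expression, since the group and the named background coincide. Fewer macrophages and B cells remain open: macrophage markers had a median of -0.11 (SD 0.54), with the abundant Lyz2, C1qa and Csf1r at -0.28, 0.27 and -0.05 but the less abundant Cx3cr1 and Adgre1 at -1.53 (adjusted p = 0.0546) and -1.0 (adjusted p = 0.235), and the 3 B cell markers tested -1.14. Whether T and NK cells were fewer could not be tested as a list. Of their 14 markers 1 passed the filter, Cd247 at -1.13 (edgeR adjusted p = 0.343). Of 8 thymus markers 2 did, Tcf7 at -1.55 (0.269) and Cd1d1 at -0.22 (0.862). A strain difference in interferon signalling or an effect of diabetes was not tested.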
